A study of Mus musculus with 84 samples.

How the data were processed

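The series holds 84 samples of mouse placenta. Of these, 36 are input libraries that have no file of their own and were not used here, except that the submitters called peaks against them. The other 48 are peak lists, 1 per ChIP-seq library. The time course has 24 libraries of H3K4me3Q5ser, histone H3 that carries trimethylated lysine 4 and serotonin bound to glutamine 5, from 8 placentas at each of E9.5, E12.5 and E17.5, 4 male and 4 female. The genotype set has 12 placentas of E12.5, 3 each of wild type (WT), Sert KO, Tph1 KO and Oct3 KO, and each was profiled for both H3K4me3Q5ser and H3K4me3, histone H3 with trimethylated lysine 4. Sert is the plasma membrane serotonin transporter (gene Slc6a4), Tph1 the enzyme of serotonin synthesis outside the brain, and Oct3 an organic cation transporter (gene Slc22a3). Per the labels, hemisected placentas were fixed with formaldehyde and sheared by sonication, and the antibodies came from MilliporeSigma (H3K4me3Q5ser) and Active Motif (H3K4me3).

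Each library was called alone by the submitters against the input of the same placenta. Per the file headers, MACS2 2.2.6 with a q cutoff of 0.01 made the time course lists, MACS2 2.2.7.1 with a q cutoff of 0.05 the H3K4me3Q5ser lists of the genotype set, and MACS2 2.1.1.20160309 with a q cutoff of 0.05 the H3K4me3 lists. The processing notes name HISAT 0.1.6b, MACS2 2.1.1, DiffBind 3.8.4 and the build mm10. The deposited lists hold the position and width of each called peak in bp. Per the file headers, the pileup is a signal, the number of fragments stacked at the summit after scaling of the library and its input. The deposited significance values are -log10 p and -log10 q of a Poisson test against the local input background. The fold enrichment is a ratio of the library over the local input background at the summit, per the file headers. These scores are the authors' own, and they served only to rank or filter peaks within a list.

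Depth is given by the headers. The time course libraries had 11.2 to 35.2 megatags, of which 8.43 to 25.4 megatags were left after duplicates were removed, and the genotype libraries had 9.91 to 24.0 megatags. The lists hold no read counts per gene, so no counting interval can be given for a gene, and a promoter without a called peak is one where no peak was called at this depth, not one shown to lack the mark.

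Peaks on 21 chromosomes were joined to 21886 genes (21883 protein-coding and 3 others that the gene lists name) of the GRCm38.p6 gene table, which gives the start and end of each gene but neither strand nor transcript starts. The plan had called for transcript starts. In their place, each gene was represented by the gene end whose window of 1 kb each side was marked in more of the 48 libraries, whatever their group, or by both ends when these tied. At 12425 genes only 1 end was ever marked, at 2210 both were, and at 7251 neither was. The word promoter refers to this gene end throughout. A promoter was marked in a library when a peak covered at least 1 bp of that window. Promoter width was the number of bp covered by peaks within 2 kb of the same end.

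Occupancy was compared by a two-sided Fisher's exact test per promoter on the numbers of marked and unmarked libraries, adjusted by Benjamini-Hochberg over the promoters whose total allowed a p of 0.05, with a threshold of 0.05. With 3 against 3 the smallest two-sided p is 0.1, so for each knockout the promoters marked in 3 of 3 placentas of 1 group and 0 of 3 of the other were counted without a test. Widths were scaled so that promoters marked in every library of a fit had the same median, promoters with a mean under 200 bp were removed, and log2 of the scaled width plus 200 bp was fitted with limma 3.58.1 (lmFit, eBayes with trend), with sex as a covariate in the time course. The change of H3K4me3Q5ser relative to H3K4me3 was the difference of both log2 widths within a placenta, fitted by genotype. In this fit the placenta is the replicate block. The labels pair the marks by placenta. This pairing was checked by the correlation, across genes, of each library's deviations from its genotype mean, which ran from -0.0371 to 0.362 (median 0.185) and was highest for the placenta's own partner in 11 of 12 placentas.

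The 23 gene lists (452 distinct genes) were trophoblast stem and progenitor cells, trophoblast giant cells, spongiotrophoblast and glycogen trophoblast, placental cathepsins, labyrinth syncytiotrophoblast, nutrient transport, steroid synthesis, endothelium, pericytes and mesenchyme, erythroid cells, macrophages and other leukocytes, decidual stroma, uterine natural killer cells, yolk sac endoderm, serotonin synthesis, transport and breakdown, imprinted genes, neural transcription factors, axon guidance and synapse genes, Hox genes, hypoxia and angiogenic signals, cell cycle, housekeeping controls and a sex-linked label check. The table lacked 2 of the listed names, and 1 was found under its present symbol. The share of a list's promoters marked in each library was compared by a two-sided exact permutation test. Lists, comparisons, tests, thresholds and the rule for named genes were fixed before the data were examined.

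The rule for named genes took, per stage contrast and direction, the 10 promoters past the test with the largest difference in marked libraries, then in covered bp, and up to 4 passing members of each list, or 2 members as values if none passed. For widths it took the 5 smallest adjusted p per direction, or the 3 smallest unadjusted p if none passed, and for the counts of 3 of 3 against 0 of 3 the 3 largest differences in covered bp per direction. For the comparison of marks it took 5 promoters. Members of the lists whose widths are given beyond this rule were chosen after their values were seen. The prolactin (Prl), pregnancy-specific glycoprotein (Psg), Ceacam and cathepsin (Cts) families hold near-identical copies that can share reads.

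File names in the headers of the time course lists name 2 pools, taken here as sequencing pools. Each held 4 placentas of every stage, and values within each pool, or for promoter occupancy counts stratified by pool, stand beside the pooled ones. In the genotype set the lane sets were unevenly spread over the genotypes, with all Sert KO placentas in 1 lane set. Other choices tried were peaks with -log10 q of 5 or more, the same number of peaks in each library, an overlap of 200 bp, a 2 kb window, pseudocounts of 50 bp and 1 kb, no filter, no scaling, no covariate, analysis with and without the replicate block, and leaving out each library. Either gene end as promoter, the pool or lane set, and the fragment length as covariates were alternatives chosen after seeing the data.

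The procedure was tested on simulated data built from the real lists. Each promoter was drawn on its own in each library. Differences that many promoters of a library share, as with peak number, and the pairing of marks were thus not simulated. The false calls given here do not measure error from such differences. Width changes were placed only at promoters of intermediate width. For E17.5 against E9.5 the occupancy test recovered 81 of 100 promoters simulated at 95% against 5% marked and 14 of 100 at 80% against 20%, with 1 false call in 96. For both marks it recovered 97 and 31 of 100, with 0 false calls in 128. The width fit recovered 90% of 1.5-fold and 93% of 2-fold changes between stages (11 false of 194 calls), 45% and 64% for Sert KO in H3K4me3Q5ser (2 false of 111), 35% and 80% in H3K4me3 (5 false of 120), and 6.25% and 22.7% for the relative change (0 false of 22). Scripts ran under Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3.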

Results

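Promoter marking by H3K4me3Q5ser was followed in 24 mouse placentas, 8 at each of 3 stages, E9.5, E12.5 or E17.5 (4 male and 4 female per stage), and by H3K4me3Q5ser and H3K4me3 together in 12 placentas of E12.5, 3 per genotype. In the time course, 26055 ± 1590 peaks were called per library at E9.5, 23696 ± 1600 at E12.5 and 22736 ± 1221 at E17.5 (SD, n = 8 each). In the genotype set, H3K4me3Q5ser gave 26525 ± 3746 peaks and H3K4me3 18661 ± 2311 (SD, n = 12 each). Sequencing depth ran from 11.2 to 35.2 megatags in the time course and from 9.91 to 24 megatags in the genotype set. Counts of marked libraries are given as libraries with a peak out of all libraries of the group, covered lengths as bp ± SD, and positions on mm10. Lengths beside such counts are covered bp within 1 kb of the gene end used, and promoter widths are those within 2 kb. The p-values measure the spread between separate placentas, with 2 exceptions. The Fisher's exact test between the marks counts both libraries of a placenta as separate, and the tests of gene families take genes as units.

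The genes that the knockouts target were read first. Slc6a4 (11:76998597-77032343), which encodes the serotonin transporter Sert, was marked by H3K4me3Q5ser in 8 of 8 placentas at every stage, over 1175 ± 185 bp at E9.5, 1395 ± 119.04 bp at E12.5 and 1422 ± 54 bp at E17.5. Its promoter width was larger at E12.5 than at E9.5 (log2 change 0.18 ± 0.05 SE, adjusted p = 0.023, 8 and 8 placentas), a call that was lost without scaling, with the same number of peaks per library, with fragment length as a covariate and without the placenta E12.5F_65, and the next step was 0.08 ± 0.05 (adjusted p = 0.39). Slc22a3 (17:12419972-12507704), which encodes the organic cation transporter Oct3, was marked in 2 of 8 placentas at E9.5, 6 of 8 at E12.5 and 8 of 8 at E17.5, and E17.5 exceeded E9.5 (Fisher's exact test, adjusted p = 0.016). Its promoter covered 59.6 ± 113 bp at E9.5, 493 ± 402 bp at E12.5 and 868 ± 50.2 bp at E17.5. No peak was called at the ends of Tph1 (7:46644641-46672537), the enzyme of peripheral serotonin synthesis, in any of the 48 libraries. In the genotype set, Slc6a4 was marked by H3K4me3Q5ser in 3 of 3 placentas of each genotype, over 831 ± 432 bp in WT, 770 ± 105 bp in Sert KO, 867 ± 317 bp in Tph1 KO and 1020 ± 479 bp in Oct3 KO. H3K4me3 marked Slc6a4 in 2 of 3 WT, 0 of 3 Sert KO, 1 of 3 Tph1 KO and 1 of 3 Oct3 KO placentas. Slc22a3 was marked by H3K4me3Q5ser in 0 of 3 WT, 2 of 3 Sert KO, 1 of 3 Tph1 KO and 0 of 3 Oct3 KO placentas. Where the deletions lie within these genes is not stated in the labels, so a peak at the promoter does not test the knockouts.

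The step from E9.5 to E12.5 addressed how H3K4me3Q5ser changes as the mature placenta forms. Promoters of the spongiotrophoblast, the junctional layer of the mouse placenta, gained the mark at E12.5. Tpbpa (13:60938492-60941936), the marker gene of the spongiotrophoblast, was marked in 8 of 8 placentas at E12.5 over 900 ± 92 bp and in 0 of 8 at E9.5. Its relative Tpbpb (13:60901295-60904847) went from 0 of 8 to 7 of 8 (475 ± 313 bp). The pregnancy-specific glycoprotein genes Psg25 (742 ± 228 bp) and Psg27 (673 ± 338 bp) went from 0 of 8 to 8 of 8, and Psg19 from 0 of 8 to 7 of 8. Prl7d1, a placental prolactin relative, went from 1 of 8 to 8 of 8. Further gains from 0 of 8 to 8 of 8 were Ccr1l1 (9:123976430-123986715, 859 ± 115 bp), a gene related to chemokine receptors, and Ccdc120 (X:7731714-7741324, 818 ± 119.1 bp). So were Ccdc92b (789 ± 180 bp), the core clock gene Arntl (713 ± 287 bp) and Trim10 (678 ± 230 bp). Sh3tc1 (1066 ± 82 bp) and the X-linked Xlr3a (840 ± 349 bp) went from 1 of 8 to 8 of 8. The red cell membrane genes Slc4a1 (anion exchanger), Rhd (blood group antigen) and Epb42 (membrane skeleton protein) were marked in 0 of 8 placentas at E9.5 and 6 of 8 at E12.5 (adjusted p = 0.034, Fisher's exact test).

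Marks were lost at E12.5 from 8 of 8 to 0 of 8 placentas at Dpep1 (8:123186235-123201812), a dipeptidase gene covered over 946 ± 292 bp at E9.5. The same loss was found at the ferroxidase gene Hephl1 (870 ± 137 bp), Vwc2 (753 ± 201 bp) and Vwf (611 ± 269 bp), which encodes von Willebrand factor of endothelium. It was also found at the tight junction gene Cldn15 (551 ± 260 bp), AU021092 (479 ± 199 bp) and the metalloproteinase gene Adamts16 (432 ± 160 bp). Serpina3n (386 ± 137 bp), a protease inhibitor gene, and Armt1 (298 ± 144 bp) lost the mark as well. Fam167b went from 8 of 8 to 1 of 8. Other members named by list did not pass. The endothelial gene Egfl7 was marked in 8 of 8 and then 3 of 8 (adjusted p = 0.068, Fisher's exact test), and the pericyte gene Rgs5 in 2 and then 7 of 8 (0.092). Pax6 was marked in 7 and then 2 of 8 (0.092) and the nerve growth factor receptor gene Ntrk1 in 5 and then 0 of 8 (0.068; all Fisher's exact test). In total 147 of 625 testable promoters differed by two-sided Fisher's exact test, 51 more and 96 less often marked at E12.5. At an unadjusted p under 0.05 there were 276. Stratified by sequencing pool, the exact test gave 141 promoters, 50 more and 91 less often marked. Changes from 0 to 8 of 8 had p = 0.000155 and adjusted p = 0.0057 (Fisher's exact test). Taking the same number of peaks in each library, 72 were more and 51 less often marked, and 58 of the 147 were still called. Vwf, Cldn15, AU021092, Adamts16, Serpina3n, Armt1, Tpbpb, Slc4a1, Rhd and Epb42 then no longer passed.

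Promoter width gave more resolution, since it also covers promoters marked at every stage. Aqp3 (4:41092724-41098183), a channel for water and glycerol, widened from 538 ± 148 to 2084 ± 143 bp (log2 change 1.65 ± 0.09 SE, adjusted p = 4e-12, n = 8 and 8, limma). Tpbpa widened from 32 ± 91 to 1658 ± 269 bp (3.05 ± 0.13), with Ccr1l1 (2.80 ± 0.10), Ccdc120 (2.55 ± 0.10) and Sh3tc1 (2.64 ± 0.14) also higher. Hsd17b1, an enzyme of estradiol synthesis, narrowed from 2265 ± 240 to 1430 ± 70 bp (-0.60 ± 0.04), and the transcription factor gene Sox8 from 2965 ± 228 to 1716 ± 166 bp (-0.73 ± 0.05). The peptidase inhibitor gene Pi15 narrowed from 1584 ± 370 to 44 ± 125 bp (-2.95 ± 0.19), and Hephl1 (-2.89 ± 0.18) and Vwc2 (-2.59 ± 0.18) lost all covered bp. Log2 changes against a group without covered bp depend on the pseudocount. In all, 2299 of 13656 promoters differed, 1056 wider and 1243 narrower at E12.5, 3955 at an unadjusted p under 0.05. The sign was the same in both pools for 2298 of them, which a call from the pools together nearly forces. Within either pool alone, 1135 and 738 promoters passed.

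Among imprinted genes, 12 of 23 promoters widened at E12.5 and 1 narrowed. Zim1 changed by 1.57 ± 0.10 (adjusted p = 3.5e-11), the growth factor gene Igf2 by 1.94 ± 0.42 (0.0017), Peg3 by 0.42 and H19 by 0.30. Endothelial promoters went the other way, with 11 of 18 narrower and 1 wider. Egfl7 changed by -2.31, the receptor genes Tie1 by -1.15 and Tek by -0.90, Emcn by -1.14 and Sox17 by -0.59, against 0.49 for Plvap. Of the spongiotrophoblast list 12 of 18 widened and none narrowed. Axon guidance and synapse promoters narrowed at 8 of 24, among them Ntrk1 (-1.17) and the glutamate receptor gene Grin1 (-0.63). Of 34 Hox promoters 9 narrowed, such as Hoxd11 (-0.84), and 1, Hoxa13 (0.85), widened. In the serotonin list, the vesicular transporter gene Slc18a2 (0.53) widened with Slc6a4, Slc22a3 and Slc18a1, while the tryptophan dioxygenase gene Tdo2 (-1.75) and the receptor gene Htr2a (-0.35) narrowed. Trophoblast stem cell promoters went both ways, with 5 wider (Cdx2 0.45) and 2 narrower (Eomes -0.33) of 18. The other lists gave 5 wider and 1 narrower of 13 for labyrinth, 5 and 2 of 15 for nutrient transport and 3 and 0 of 6 for giant cells. There were 1 and 0 of 3 for cathepsins, 4 and 0 of 6 for erythroid cells, 2 and 1 of 11 for pericytes, and 1 and 0 of 7 for yolk sac endoderm. Narrower promoters were the more frequent for steroid synthesis (0 wider and 3 narrower of 10), macrophages (0 and 2 of 9), decidual stroma (1 and 4 of 16) and uterine natural killer cells (0 and 3 of 4). Neural transcription factors gave 3 and 2 of 28, hypoxia 0 and 1 of 19, sex-linked genes 2 and 0 of 9, and housekeeping controls 0 and 0 of 19. Some splits depended on the scaling, here given first without it and then at equal peak numbers. Hox genes had 1 wider and 4 narrower, then 3 and 8, and decidual stroma 0 and 1, then 1 and 4. Nutrient transport had 2 and 0, then 5 and 1, the serotonin list 2 and 2 both times, neural transcription factors 2 and 2, then 5 and 2, trophoblast stem cells 5 and 1 both times, and hypoxia 0 and 0, then 0 and 2.

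Between E12.5 and E17.5, the second step of the time course, further placental hormone and protease genes gained H3K4me3Q5ser. The prolactin family genes Prl8a6 (754 ± 108 bp) and Prl8a8 (509 ± 180.6 bp) and the cathepsin gene Cts6 (692 ± 217 bp) went from 0 of 8 to 8 of 8 placentas. Ceacam11 went from 1 of 8 to 8 of 8 (860 ± 188 bp) and Ceacam14 from 0 of 8 to 7 of 8. Pax8 (2:24420551-24475599), a paired box transcription factor gene, also went from 0 of 8 to 8 of 8 (796 ± 155 bp), with the coagulation factor gene F11 (749 ± 214 bp), Sparcl1 (665 ± 142 bp) and AU021092 (619 ± 198 bp). Mchr1, a receptor for melanin-concentrating hormone, went from 0 of 8 to 7 of 8. Marks at AU021092 were thus present in 8, 0 and 8 of 8 placentas over the 3 stages in turn.

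Marks were lost at E17.5 from 8 of 8 to 0 of 8 placentas at Ccdc92b (789 ± 180 bp at E12.5) and Trim10 (678 ± 230 bp), both gained at E12.5. They were also lost at Gabrg1 (563 ± 313 bp), a GABA receptor gene, and Gad1 (2:70561303-70602014, 175 ± 134 bp), the enzyme of GABA synthesis. The same loss was seen at Sptssb (a subunit of serine palmitoyltransferase; 482 ± 317 bp), Clvs2 (437 ± 77 bp), the lipoxygenase gene Alox8 (387 ± 95 bp), Trim58 (376 ± 114 bp), Csrnp3 (361 ± 104 bp) and Btbd18 (138 ± 51 bp), whose promoter window also holds an end of Selenoh. Slc4a1 and Rhd were marked in 6 and then 0 of 8 placentas, and Ctsq in 0 and then 6 of 8, all at an adjusted p of 0.0501 that did not pass (Fisher's exact test). Tdo2 and Prl8a2 were marked in 7 and then 1 of 8 (0.058), and the synapse gene Nlgn1 likewise. Altogether 35 of 537 testable promoters differed, 14 more and 21 less often marked at E17.5, and 35 when stratified by pool. Leaving out 1 placenta gave 38 to 95 promoters, with 91 to 95 without E17.5M_36, E12.5F_79, E12.5F_80, E12.5M_81 or E12.5F_132. There were 165 at an unadjusted p under 0.05. Changes between 0 and 8 of 8 had p = 0.000155 and adjusted p = 0.0046 by Fisher's exact test. The count was 76 with a 2 kb window or with either gene end as promoter. Pax8 and Btbd18 did not pass with the 2 kb window, nor Gad1, Btbd18 and Sptssb when a peak had to cover 200 bp. At the same number of peaks per library the split was 22 more and 17 less often marked, with 22 of the 35 still called. Then Ceacam14, Mchr1, Gabrg1, Sptssb, Clvs2, Alox8, Trim58 and Csrnp3 no longer passed.

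By width, Fdps (3:89093588-89101967), an enzyme of isoprenoid and sterol synthesis, narrowed from 2589 ± 139 to 1676 ± 75 bp between E12.5 and E17.5 (-0.55 ± 0.03 SE, adjusted p = 9.6e-12, n = 8 and 8). Gad1 fell from 763 ± 330 bp to 0 bp (-2.19 ± 0.15), and Csrnp3 (-2.07 ± 0.10), Ccdc92b (-2.83 ± 0.17) and Clvs2 (-1.65 ± 0.11) lost all covered bp. The kinase gene Pak1 widened from 1430 ± 92 to 2196 ± 257 bp (0.58 ± 0.05), and Hif3a, of the hypoxia-inducible factor family, from 1708 ± 247 to 2742 ± 77 bp (0.66 ± 0.05). Prl8a6 (2.95 ± 0.13), Cts6 (3.01 ± 0.16) and F11 (2.66 ± 0.19) were the other leading gains. Slc22a3 widened by 0.97 ± 0.32 (adjusted p = 0.041), a call lost without scaling, with a pseudocount of 50 bp, with fragment length as a covariate and on leaving out any of 11 single libraries.

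Cell cycle promoters were marked at every stage, and 14 of 20 narrowed at E17.5 (median log2 change -0.29; 14 also without scaling and with the same number of peaks). Plk1 changed by -0.55 (adjusted p = 1.9e-07), Ccnb1 by -0.53 and the proliferation gene Mki67 by -0.52 (4.3e-10). Cdc20 changed by -0.51, Top2a by -0.41, the replication gene Mcm5 by -0.38 (6.1e-08) and Pcna by -0.29, while Ccnd2 alone widened (0.58, 0.0065). Hox promoters split into 6 wider (Hoxc9 1.43, Hoxb5 0.97) and 5 narrower (Hoxd10 -1.20). The spongiotrophoblast list had 7 wider and 1 narrower, with Prl2b1 at 2.40 at E12.5 and -1.67 at E17.5. Axon and synapse promoters gave 3 wider (Slit1 1.08) and 5 narrower, and the serotonin list 2 wider (Slc22a3, Htr1d 0.12) and 2 narrower (Tdo2 -1.58, Htr1b -0.41). Plagl1 (0.51) was among the imprinted genes that widened, and the endothelial genes Tek (0.65) and Plvap (0.63) widened, while Mmrn2 (-0.92), named here after its value was seen, narrowed and no endothelial promoter did without scaling. The remaining lists had few changes, such as 3 and 0 for labyrinth and for pericytes, 2 and 0 for cathepsins, 0 and 3 for erythroid cells, 1 and 3 for macrophages, 1 and 4 for decidual stroma and 0 and 2 for housekeeping controls. In total 1895 of 13656 promoters differed, 856 wider and 1039 narrower, with 3699 at an unadjusted p under 0.05. All 1895 had the same sign in both pools, which a call from the pools together nearly forces, and 663 and 768 passed within a pool. Without scaling, 387 were wider and 992 narrower, with 0 and 2 in the serotonin list, 0 and 4 in decidual stroma, 5 and 6 for Hox genes, 1 and 0 for labyrinth and 0 and 4 for housekeeping controls. Macrophages had 0 and 2 without scaling and at equal peak numbers, and pericytes 2 and 0, then 1 and 0.

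**Figure D1:**
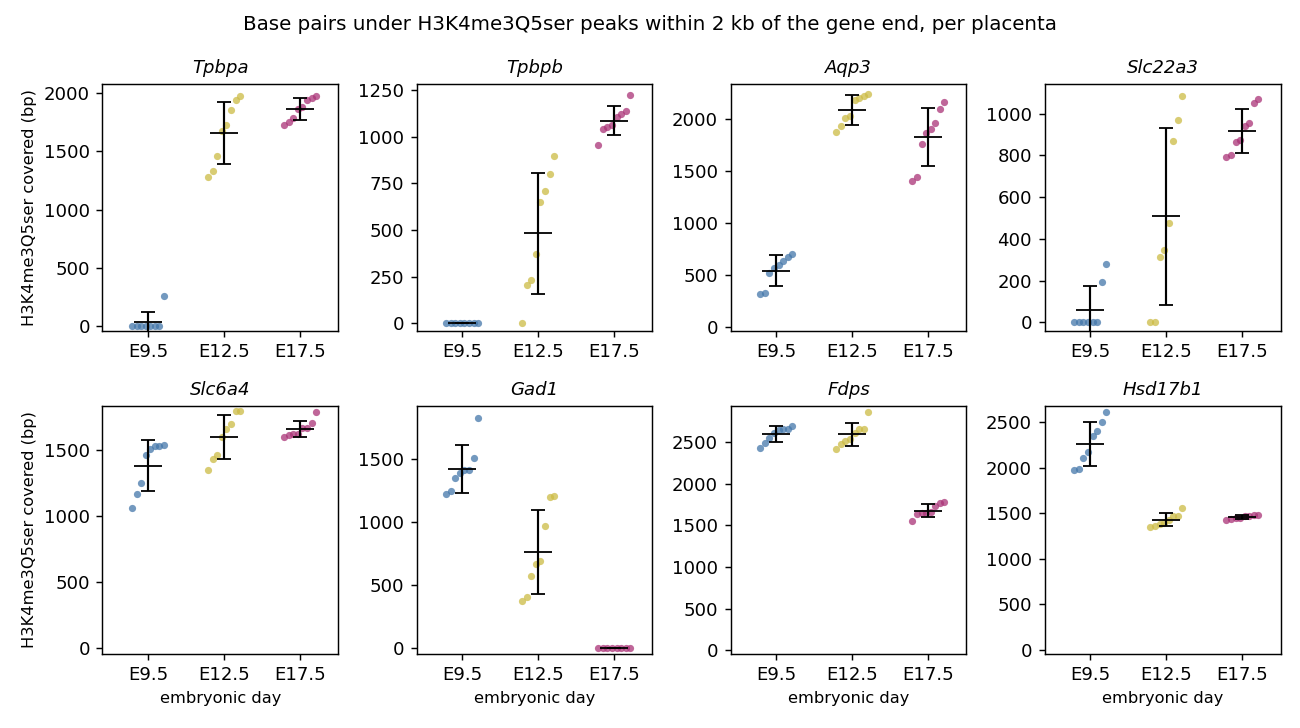
Promoter width in bp covered by H3K4me3Q5ser peaks within 2 kb of the gene end used, by embryonic stage, for 8 genes. Dots are placentas and bars are means ± SD (n = 8 per stage); Tpbpa rose from 32 ± 91 to 1658 ± 269 bp by E12.5, and Gad1 was at 0 bp in all placentas of E17.5.

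Over the whole interval from E9.5 to E17.5, spongiotrophoblast promoters stood among the largest gains of the mark. Tpbpb (1001 ± 55 bp), Tpbpa (916 ± 81 bp), Psg27 (964 ± 51 bp), Psg25 (955 ± 38 bp), Psg19 and Ceacam11 went from 0 of 8 to 8 of 8 placentas. So did the homeobox gene Evx1 (998 ± 84 bp), Ccdc120 (1068 ± 80 bp), Cpsf4l (1066 ± 221 bp), Ccr1l1 (995 ± 31 bp), Fnd3c2 (915 ± 36 bp) and the phospholipase gene Pla2g4d (902 ± 71 bp). The smooth muscle actin gene Acta2 (460 ± 140 bp), the imprinted gene Zdbf2 (369 ± 103.2 bp), the axon guidance gene Slit1 (538 ± 241 bp) and Cts6 also went from 0 of 8 to 8 of 8. Rgs5 went from 2 of 8 to 8 of 8, Hoxc8 from 0 to 7 of 8, Hoxa2 from 1 to 7 of 8, Ctsq from 0 to 6 of 8, and Cspg4 and Tbx4 from 0 to 5 of 8 (adjusted p = 0.043, Fisher's exact test). The mark was lost from 8 of 8 to 0 of 8 placentas at S100a8 (3:90669071-90670034, 1380 ± 327 bp at E9.5), which encodes a calcium-binding protein of myeloid cells, and at Gabrg1 (1186 ± 200 bp) and Astl (1165 ± 158 bp, an end shared with Dusp2). Further such losses were Sptssb (986 ± 180 bp), Egfl7 (985 ± 125 bp), Fmo2 (961 ± 103 bp), Dpep1 (946 ± 292 bp), Csmd1 (927 ± 180 bp), Prom2 (873 ± 278 bp) and Hephl1 (870 ± 137 bp). In the serotonin list, the mark was lost at the tryptophan dioxygenase gene Tdo2 from 8 of 8 (1056 ± 91 bp) to 1 of 8, and at the monoamine oxidase gene Maob from 7 of 8 to 0 of 8. Losses at neural genes included Nlgn1 (8 to 1 of 8), Pax6 (7 to 0), Sema3a (6 to 0) and Ntrk1 (5 to 0), and at genes of myeloid cells Tyrobp (6 to 0) and Fcer1g (8 to 3, an end shared with Ndufs2). Prl8a2, a hormone gene of the decidua, went from 8 to 1 of 8 and the steroid enzyme gene Hsd3b6 from 6 to 0 of 8.

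For this interval 442 of 742 testable promoters differed by Fisher's exact test, 320 of them less and the rest more often marked at E17.5, 470 at an unadjusted p under 0.05. Changes between 0 and 8 of 8 had p = 0.000155 and adjusted p = 0.0012 (Fisher's exact test). Stratified by pool, 454 differed, 330 of them less often marked. When every library had the same number of peaks, 177 were more and 185 less often marked, and 262 of the 442 were still called. Maob, Pax6, Sema3a, Ntrk1, Tyrobp, Hsd3b6, Hoxc8, Cspg4 and Tbx4 then no longer passed. A 2 kb window ended the calls at Astl, Nlgn1 and Ntrk1, a stricter q those at Cspg4 and Ntrk1, and an overlap of 200 bp that at Sema3a.

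Taken by list, the share of spongiotrophoblast and glycogen trophoblast promoters with H3K4me3Q5ser rose from 16 ± 3.90% at E9.5 to 39.5 ± 9.44% at E12.5 and 57.4 ± 4.99% at E17.5 (32 genes; SD, n = 8 per stage; adjusted p = 0.00179 for both steps, exact permutation test). The steps were 24.2 and 22.7 percentage points in the 2 pools, then 17.2 and 18.8. Erythroid promoters rose from 23.5% to 38.2 ± 7.70% and fell to 21.3 ± 3.04% (17 genes; adjusted p = 0.00179 for both, exact permutation test; pools 16.2 and 13.2, then -17.6 and -16.2). Cathepsin promoters, at 7.81 ± 6.47% and 18.8 ± 11.6% at the first stages, rose to 42.2 ± 9.30% at E17.5 (8 genes; adjusted p = 0.0174, exact permutation test; pools 25 and 21.9). Pericyte and mesenchyme promoters rose from 64.1 ± 5.54% at E12.5 to 78.1 ± 6.68% at E17.5 (16 genes; adjusted p = 0.0174, exact permutation test; pools 20.3 and 7.81), from 55.5 ± 6.19% at E9.5. Macrophage promoters fell from 47.9 ± 6.60% to 36.8 ± 4.13% at E17.5 (18 genes; adjusted p = 0.0174, exact permutation test; pools -6.94 and -15.3), from 52.8 ± 7.27% at E9.5. The serotonin list stood at 56.8 ± 4.42% and 55.2 ± 2.95% and fell to 50 ± 2.23% at E17.5 (24 genes; adjusted p = 0.0322, exact permutation test; pools -5.21 and -5.21). In each of these 8 calls, all 8 placentas lay on the same side of the other stage's mean. Given the same number of peaks per library, the calls for erythroid cells (adjusted p = 0.126 and 0.0894), pericytes (0.109) and macrophages (0.0894) were lost (exact permutation test), and their directions stayed.

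Single members tell which genes carried these shares. In the spongiotrophoblast list 7 promoters gained the mark at E12.5 and 4 at E17.5 (8 and 4 adjusted over the list alone), and 12 were gained and 1 lost between E9.5 and E17.5. In the erythroid list 3 gained it at E12.5, and 0 passed at E17.5, where 3 were lower when adjusted over the list alone. Among cathepsins 1 passed at E17.5 (2 adjusted over the list alone), in the macrophage list 0 (2 lower adjusted over the list alone). In the serotonin list 0 passed at E17.5 as well (1 lower adjusted over the list alone). From E9.5 to E17.5, 4 pericyte promoters were gained, 2 macrophage promoters were lost (3 adjusted over the list alone), and in the serotonin list 1 was gained and 2 were lost.

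The other 17 lists did not pass at either step. Endothelial promoters were marked at 100, 95.8 and 91.0% at the 3 stages (adjusted p = 0.106 for both steps, exact permutation test), and imprinted genes at 78, 80.6 and 82.8% (0.106 for both). The imprinted list passed at the first step with the same number of peaks and at both when divided by the share of all genes marked. Axon and synapse genes were at 71.1, 66.0 and 64.5%, Hox genes at 75.6, 79.8 and 82.4%, and uterine natural killer cells at 30.5, 21.9 and 20.3%. Decidual stroma was at 99.2, 98.4 and 92.2%, hypoxia genes at 92.5, 93.1 and 88.8%, yolk sac endoderm at 33.6, 43.0 and 35.9%, steroid synthesis at 76.0, 70.8 and 72.9%, giant cells at 34.6, 34.6 and 37.5%, and trophoblast stem cells at 87.5, 85 and 85%. Neural transcription factors were at 71.7, 72.4 and 72.8% and sex-linked genes at 73.6, 77.8 and 77.8%. Labyrinth (72.2%), nutrient transport (83.3%), cell cycle (100%) and housekeeping promoters (95%) had the same share at all stages.

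**Figure D2:**
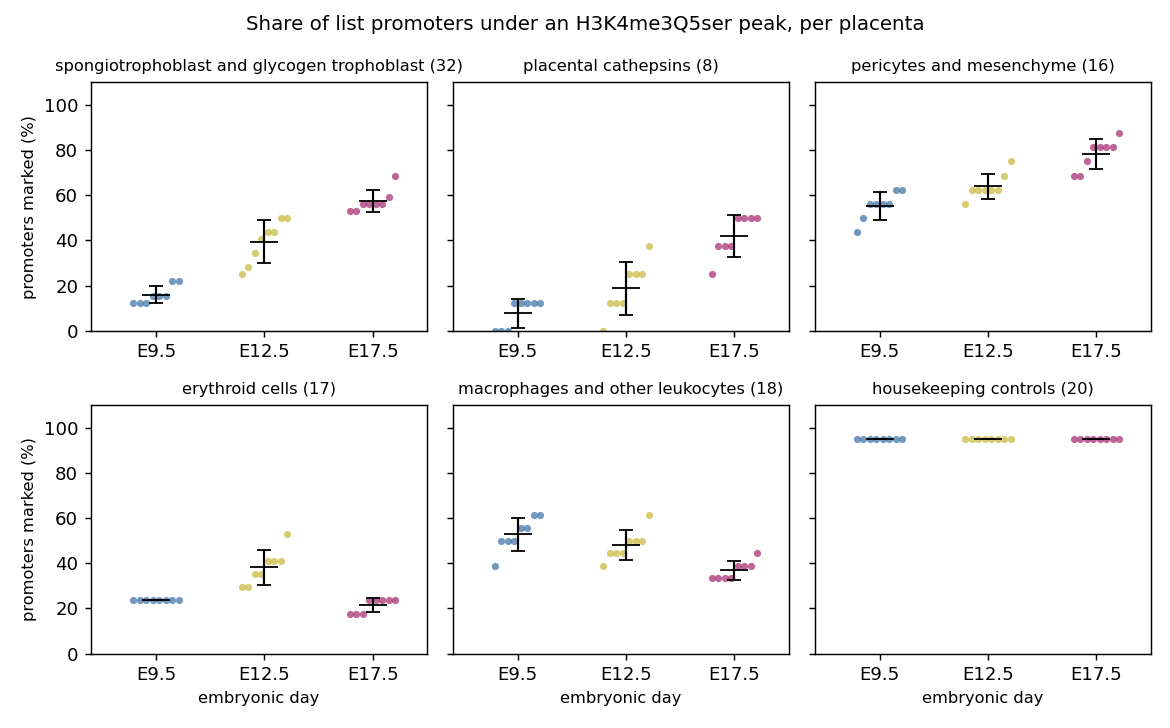
Percent of the promoters of 6 gene lists marked by H3K4me3Q5ser, by embryonic stage. Dots are placentas and bars are means ± SD (n = 8 per stage); the spongiotrophoblast list rose from 16 to 57.4%, and erythroid promoters peaked at 38.2% at E12.5.

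The peak lists as a whole also differed by stage. The number of peaks differed by -3319 between E17.5 and E9.5 (adjusted p = 0.00373, exact permutation test; pools -2031 and -4606). Of the steps the first passed (-2359, adjusted p = 0.0182; pools -2271 and -2446) and the second did not (-960, p = 0.196; pools 240.5 and -2160; exact permutation test). Median peak width rose from 952 ± 75.3 bp at E9.5 to 1050 ± 70.0 bp at E12.5 (adjusted p = 0.0398, exact permutation test; n = 8 each; pools 85.4 and 110) and was 1120 ± 74.3 bp at E17.5 (adjusted p = 0.111 for the second step, 0.00373 against E9.5, exact permutation test). The share of peaks within 1 kb of a gene end was 53.7 ± 3.03, 57.3 ± 3.61 and 58.3 ± 1.76%, and E17.5 exceeded E9.5 by 4.59 points (adjusted p = 0.00746, exact permutation test; pools 1.89 and 7.29). Covered length was 32.5 ± 2.27, 30.9 ± 3.0 and 29.9 ± 1.45 Mb, lower at E17.5 than at E9.5 by -2.55 Mb (adjusted p = 0.0398, exact permutation test; pools -1.20 and -3.91). On average 13397, 13266 and 13147 promoters were marked.

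Male and female placentas were compared to see whether sex alters the mark. Among 974 testable promoters 4 differed, all on the Y chromosome. The helicase gene Ddx3y was marked in 12 of 12 males (p = 7.4e-07, adjusted p = 0.00072, Fisher's exact test) and Kdm5d, Uty and Eif2s3y in 11 of 12 (p = 9.6e-06, adjusted p = 0.0023), against 0 of 12 females, and 14 promoters had an unadjusted p under 0.05. The X-linked genes Xist, Kdm5c, Kdm6a, Ddx3x and Eif2s3x were marked in 12 of 12 of both sexes. Within a stage, with 4 males against 4 females, 0 promoters passed at each stage, with 3, 15 and 6 in stage order at an unadjusted p under 0.05 (Fisher's exact test). Gene lists were compared between the sexes within each stage only after their values were seen. The spongiotrophoblast list at E12.5 stood at 46.9 ± 3.61% in males and 32.0 ± 6.93% in females, and cathepsins at 28.1 ± 6.25 and 9.38 ± 6.25% (n = 4; p = 0.0286 and adjusted p = 0.943 for both, exact permutation test). These were the 2 of 66 comparisons without overlap, or 3.03%, where chance gives at most 2.86%, and less for lists whose shares tie between placentas. With the same number of peaks per library the spongiotrophoblast list at E12.5 stood at 41.4 ± 8.22 and 26.6 ± 3.125%. Cathepsins then stood at 15.6 ± 6.25 and 6.25 ± 7.22% (p = 0.286, exact permutation test). All male libraries of E12.5 were deeper than all female ones, so sex and depth cannot be told apart there. At E9.5 and E17.5 the spongiotrophoblast list differed by -3.91 and -2.34 points (males minus females).

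The genotype set allowed H3K4me3Q5ser to be compared with H3K4me3 in the same 12 placentas. Promoters of neural transcription factors and Hox genes were marked far more often by H3K4me3Q5ser. Irx5 (8:92357796-92361456; 1227 ± 505 bp), Sox11 (1226 ± 519 bp), Zic2 (1086 ± 408 bp) and En2 (1011 ± 344 bp), all transcription factors of the embryo, and the quinone reductase gene Nqo1 (1034 ± 356 bp) were marked in 12 of 12 H3K4me3Q5ser and 0 of 12 H3K4me3 libraries (Fisher's exact test, p = 7.4e-07, adjusted p = 1.9e-05). Neural transcription factor promoters were marked at 57.1 ± 9.67% by H3K4me3Q5ser and 11 ± 4.54% by H3K4me3 (19 of 34 passing, 19 also when adjusted over the list alone). Hox promoters stood at 56.4 ± 13.3 and 20.5 ± 10.3% (17 of 39), and endothelial promoters at 72.2 ± 17.6 and 31.9 ± 10.4% (10 of 18). Axon and synapse promoters stood at 54.9 ± 7.23 and 30.2 ± 6.15% (8 of 32; SD, n = 12). At equal peak numbers per library these shares were 13.2 and 0.735% for neural transcription factors, 18.6 and 8.76% for Hox genes, 22.7 and 19.4% for endothelium, and 31.0 and 17.2% for axon and synapse genes.

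Shares in the further lists, H3K4me3Q5ser first, were 40.9 and 18.2% for spongiotrophoblast (9 passing), 80.8 and 65.8% for trophoblast stem cells (5), and 35.3 and 22.4% for giant cells (2). They were 14.6 and 2.08% for cathepsins (0), 71.8 and 62.0% for labyrinth (1), 80.1 and 70.8% for nutrient transport (1), and 58.3 and 37.5% for steroid synthesis (4). Shares were 42.2 and 11.5% for pericytes (6), 19.1 and 16.2% for erythroid cells (1), 29.2 and 14.8% for macrophages (3), and 77.6 and 47.9% for decidual stroma (3). They were 18.8 and 7.81% for uterine natural killer cells (3), 24 and 2.60% for yolk sac endoderm (5), and 41.3 and 17% for serotonin genes (6). Imprinted genes stood at 78.4 and 63.5% (5), hypoxia genes at 86.3 and 73.8% (1), cell cycle genes at 95.8 and 87.1% (1), sex-linked genes at 81.5 and 75.9% (0) and housekeeping controls at 95 and 95% (0). At equal peak numbers spongiotrophoblast stood at 9.38 and 7.29%, giant cells at 10.3 and 9.62%, and yolk sac endoderm at 0.521 and 0%. Erythroid cells were then at 10.3 and 10.3% and cathepsins at 0 and 0%. A wider gap stayed for labyrinth (63.4 and 43.5%) and hypoxia genes (67.9 and 54.2%), among others. In total 2414 of 2612 testable promoters differed, all marked more often by H3K4me3Q5ser, and 2414 had an unadjusted p under 0.05. Of these 101 went from 0 to 12 of 12. The Fisher's exact test took the 24 libraries as separate and pooled the genotypes. The count from an exact McNemar test, which pairs the marks by placenta, is given with the alternatives below. A further 8756 promoters were marked in all 24 libraries. At equal peak numbers the count was 888 of 1760 testable, all again more often marked by H3K4me3Q5ser, of which 340 were among the 2414, and Sox11, En2 and Nqo1 no longer passed. Irx5 did not pass with a 2 kb window. The antibodies and the versions of the peak caller differed between the marks, and H3K4me3 libraries held fewer and narrower peaks (498 against 646 bp), more often at gene ends (74.5 ± 2.65 against 58.4 ± 7.15%).

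**Figure D3:**
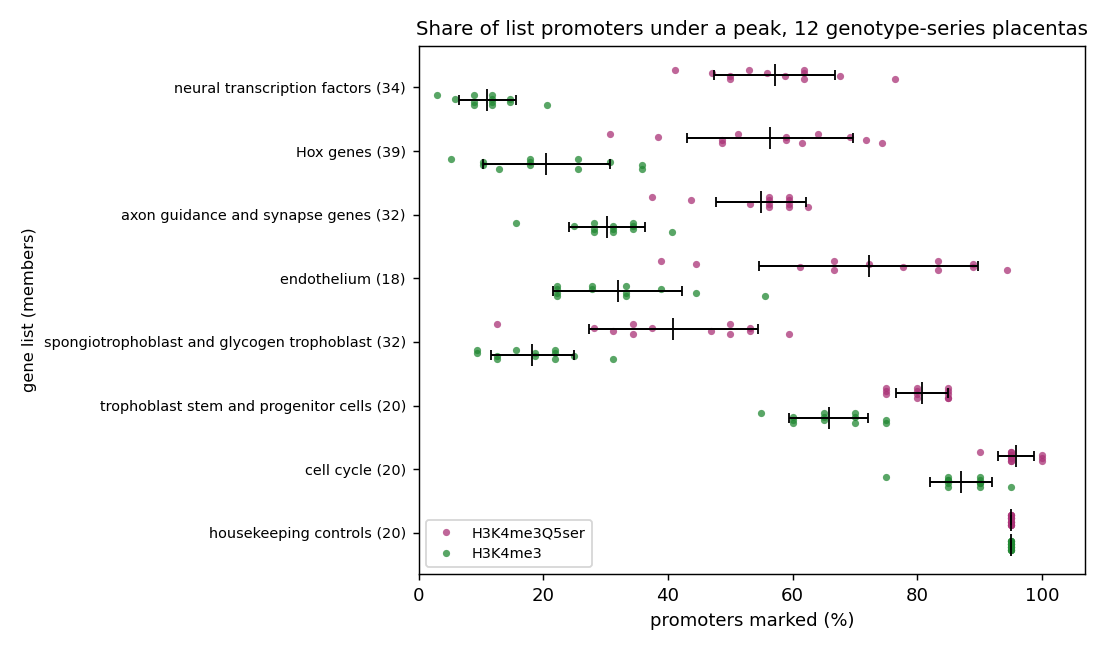
Percent of the promoters of 8 gene lists marked in the H3K4me3Q5ser and the H3K4me3 library of the same 12 placentas of E12.5, all genotypes. Dots are libraries and bars are means ± SD (n = 12); neural transcription factors stood at 57.1 against 11%, and housekeeping controls at 95% for both marks.

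Sert KO placentas were compared with WT to see which promoters depend on the serotonin transporter. For H3K4me3Q5ser, 45 promoters were marked in 3 of 3 WT and 0 of 3 Sert KO placentas and 0 the other way, of 13563 marked in at least 1 (56 to 179 when a placenta was left out). They included the ephrin receptor gene Ephb2 (762 ± 409 bp in WT), Nell2 (575 ± 52 bp), both active in axon growth, and Sfrp2 (557 ± 93 bp), an inhibitor of Wnt signals. For H3K4me3, 2 promoters were marked only in Sert KO, the GABA receptor gene Gabre (275 ± 111 bp) and Poglut3 (114 ± 35 bp), and 21 only in WT, among them Nrarp (537 ± 229 bp, a Notch-regulated gene), Rtn2 (315 ± 28 bp) and Calhm6 (306 ± 137 bp). Without Sert KO replicate 689, whose H3K4me3 library held 12948 peaks, 28 were marked only in Sert KO and 21 only in WT. Set to the same number of peaks per library, the splits were 4 Sert KO and 31 WT for H3K4me3Q5ser and 8 and 12 for H3K4me3, but only 16 of the 45 and 1 of the 23 promoters were among them. Peaks per library were 24530 ± 2103 in Sert KO and 28945 ± 4329 in WT for H3K4me3Q5ser, and 16461 ± 3050 and 19696 ± 2748 for H3K4me3 (SD, n = 3).

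With all libraries, the spongiotrophoblast list gave the 1 pair of non-overlapping groups among the 138 list comparisons of knockouts with WT. Leaving out 1 library gave 1 to 12 such pairs, and at most 4 for any library but those of WT 868. Without WT 868 there were 12 for H3K4me3Q5ser and 11 for H3K4me3, of which 10 each were lower in the knockout. Groups of 3 against 2 separate more easily, but that holds for every library left out. With all libraries, spongiotrophoblast promoters were marked by H3K4me3Q5ser at 47.9 ± 11% in Sert KO and 33.3 ± 1.80% in WT (SD, n = 3). The exact permutation p was 0.1, the smallest that 3 against 3 allow. The 1 pair is 0.725% of the comparisons, where chance gives at most 10%, and less for lists whose shares tie between placentas. With the same number of peaks per library the spongiotrophoblast values were 42.7 ± 4.77% in Sert KO and 21.9 ± 6.25% in WT. The sex of these placentas is not given, and the Y-linked Kdm5d was marked in 3 of 3 Sert KO and 2 of 3 WT placentas, so that sex was not set apart from genotype in this list. Xist was marked in 1 of 3 and 3 of 3, but it was marked in all placentas of both sexes in the time course. Trophoblast stem cell promoters stood at 76.7 ± 2.89 against 83.3 ± 2.89% and pericyte promoters at 35.4 ± 7.22 against 50 ± 13%, and for H3K4me3 axon and synapse promoters at 24 ± 7.86 against 34.4 ± 6.25% (each p = 0.2, exact permutation test). With the same number of peaks per library these were 75 against 80%, 35.4 against 37.5% and 15.6 against 15.6% in turn. By width, limma found 0 of 13079 promoters for H3K4me3Q5ser and 0 of 10769 for H3K4me3, with 366 (124 wider and 242 narrower) and 738 (299 and 439) at an unadjusted p under 0.05. Those with the smallest p for H3K4me3Q5ser, none significant, included Tst (log2 0.39 ± 0.08 SE) and Mpst (0.31), neighbours that share an end and encode enzymes of sulfur metabolism. The others were Tpgs1 (0.33), the potassium channel gene Kcnma1 (-0.70 ± 0.15), Bicc1 (-0.48 ± 0.10) and Cmc1 (-0.40 ± 0.09). For H3K4me3 they were Lamtor3 (0.54 ± 0.11), Gm38469 and Arid2 (0.42 and 0.44, a shared end), Shkbp1 (-0.70), Xaf1 (-1.69 ± 0.36) and the cell adhesion gene Cadm1 (-0.81 ± 0.18). Slc6a4 itself changed by 0.06 ± 0.25 in H3K4me3Q5ser. All Sert KO placentas were sequenced in 1 lane set, together with 1 of the 3 WT placentas, and with the lane set as covariate limma called 0 promoters for either mark.

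In Tph1 KO placentas, which lack the enzyme of peripheral serotonin synthesis, H3K4me3Q5ser marked 3 promoters in 3 of 3 knockout and 0 of 3 WT placentas, the steroid enzyme gene Cyp17a1 (463 ± 266 bp), the tight junction gene Cldn6 (295 ± 167 bp) and Cyp4f15 (260 ± 28 bp). Another 19 were marked only in WT, of 13592 marked in at least 1 placenta, among them the neurofilament gene Nefl (585 ± 190 bp), Rem1 (551 ± 253 bp) and Loxl1 (531 ± 180 bp). H3K4me3 marked 7 promoters only in Tph1 KO, such as Cldn4 (520 ± 271 bp), Serpinb9c (506 ± 357 bp) and Triml1 (424 ± 58 bp, an end shared with Triml2). It marked 5 only in WT, among them the antiviral gene Apobec3 (332 ± 154 bp), Rorb (285 ± 226 bp) and Mpp2 (254 ± 49 bp). At equal peak numbers the splits were 6 and 14 for H3K4me3Q5ser and 13 and 10 for H3K4me3, with 14 of the 22 and 8 of the 12 promoters among them. Leaving out a placenta gave 33 to 156 for H3K4me3Q5ser and 30 to 117 for H3K4me3. Cathepsin promoters stood at 20.8% in Tph1 KO and 4.17% in WT for H3K4me3Q5ser (p = 0.2), and the difference at equal peak numbers was 8.33 points (p = 0.7, exact permutation test). By width, limma called 0 promoters for either mark, with 248 (117 of them narrower) and 328 at an unadjusted p under 0.05. The smallest p values, none significant, were for H3K4me3Q5ser at Zfp619 (-0.66 ± 0.11, adjusted p = 0.60), the amino acid transaminase gene Bcat2 (-0.78), Alg8 (-0.46), Zfp972 (0.79), Grwd1 (0.50) and Arhgef16 (0.31). For H3K4me3 they were at Gm38538 (0.83), Igf2bp3 (0.33), Phf20 (0.43) and the shared end of Atf5, Nup62 and Il4i1b (-0.51).

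Oct3 KO placentas lack a low-affinity transporter of serotonin and other amines. For H3K4me3, 43 promoters were marked in 3 of 3 Oct3 KO and 0 of 3 WT placentas and 0 the other way, of 11747 marked in at least 1 (59 to 144 when a placenta was left out). They were led by the transcription factor gene Rreb1 (561 ± 322 bp), Eng (555 ± 219 bp), a coreceptor for TGF-beta in endothelium, and Epb41l4b (551 ± 121 bp). For H3K4me3Q5ser, 7 were marked only in WT and 0 only in Oct3 KO (10 to 78 when a placenta was left out), among them the nicotinic receptor gene Chrnb4 (371 ± 32 bp), Sox1 (321 ± 178 bp) and Cyp11a1 (298 ± 102 bp), the enzyme that opens steroid synthesis. Without Oct3 KO replicate 700, 71 were marked only in Oct3 KO and 7 only in WT. Its H3K4me3Q5ser library held 19633 peaks, against 31407 and 28923 for replicates 697 and 749. Equal peak numbers gave splits of 30 knockout and 2 WT for H3K4me3 and 3 and 5 for H3K4me3Q5ser, with 18 of the 43 and 1 of the 7 promoters among them. By width, limma called 1 of 10769 promoters for H3K4me3, with 382 at an unadjusted p under 0.05. E030030I06Rik (10:22113050-22149270) covered 453 ± 140 bp in Oct3 KO and 1346 ± 29 bp in WT (log2 -1.41 ± 0.18 SE, adjusted p = 0.033; SD, n = 3), lower in 3 of 3 placentas. The call was lost without scaling, with a pseudocount of 50 bp and with the lane set or fragment length as a covariate, and on leaving out any 1 of Oct3 KO replicates 700 and 749 and WT replicates 867, 868 and 873. Arid2 (0.49), Gm38469 (0.45) and Dnaaf5 (0.87) had the smallest p values among wider promoters. For H3K4me3Q5ser limma called 0 of 13079, with 292 at an unadjusted p under 0.05. The smallest p values, none significant, were at Slc46a3 (0.44), Ctnnal1 (0.36), Ttyh1 (0.34), Rnaset2a (-0.46), H2aj (-0.40) and E030030I06Rik (-1.01 ± 0.23). Without scaling, the median log2 change of all promoters was 0.16 for H3K4me3 and -0.24 for H3K4me3Q5ser relative to H3K4me3. In the housekeeping list 1 member passed by width when adjusted over the list alone.

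Sert KO was also set against the other knockouts in H3K4me3Q5ser. Against Tph1 KO limma called 0 promoters, with 304 at an unadjusted p under 0.05. The smallest p values were at Zfp619 (0.71 ± 0.11, adjusted p = 0.29), Bcat2 (0.67), Alg8 (0.42), Grwd1 (-0.48), the corepressor gene Ncor2 (-0.32) and the glutamate receptor gene Grin2d (-0.70, near Grwd1). Against Oct3 KO it called 0, with 507 at an unadjusted p under 0.05. Those with the smallest p were Rnaset2a (0.49), E030030I06Rik (1.11), Nosip (0.31), Elfn1 (-0.75), Ddhd2 (-0.42) and Nucb1 (-0.36).

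The change of H3K4me3Q5ser was also taken relative to H3K4me3 in the same placenta, a difference that carries the antibody and peak caller version as well as the mark. Here limma called 0 of 10769 promoters for each knockout, with 571 (393 higher and 178 lower) for Sert KO, 232 for Tph1 KO and 427 for Oct3 KO at an unadjusted p under 0.05. For Sert KO the smallest p values were at Cmc1 (-0.76 ± 0.14, adjusted p = 0.53), the potassium channel gene Kcnk1 (-1.46), Lyrm4 (-0.56), Naa35 (0.62), Rubcnl (1.12) and Gm3383 (1.40). Tph1 KO had them at Lxn (0.53), Apobec3 (1.55), Zfp973 (0.51), Gm38538 (-0.81), Tvp23b (-0.51) and Rasal1 (-0.82). Oct3 KO had them at the shared end of Aldh5a1 and Gpld1 (0.66), Slc46a3 (0.92), Kcnk1 (-1.40), Ppp1r16b (-2.15) and Ccm2 (-0.96), the last needed for blood vessel formation. In 24 comparisons of peak number, width, gene-end share and covered length between a knockout and WT, the smallest exact permutation p was 0.2, and all adjusted p were 1.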

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

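Of the tests in this part, those of peak number on the gained and on the lost promoters, those between both marks and the one between the pools were chosen only after the result was seen; those on all changed promoters together, on near-identical copies and on regrouped libraries were not.

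Single placentas stood apart from the other 7 of their stage in the share of marked promoters of a list. In decidual stroma, the male placenta E9.5M_118 had 93.8% against 100%, and the female E12.5F_65 had 87.5% against 100%. In yolk sac endoderm, the male E12.5M_78 had 75% against 31.3 to 50%, and in the spongiotrophoblast list the female E17.5F_34 had 68.8% against 53.1 to 59.4%. In all 78 groups of 8 were examined this way, 4 stood out, and chance alone gives about 1 in 20, or 3.9.

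Few genes passed after adjustment when the stage change of promoter width was compared between males and females. At Psg18 (7:18345744-18355038), a member of the pregnancy-specific glycoprotein family with near-identical copies, the change from E9.5 to E12.5 was larger in males by 2.19 on the log2 scale and the next step differed by -2.20. Its promoter covered 0 bp at E9.5, 808 ± 396 bp in males (4 of 4) and 0 bp in females at E12.5, and 1395 ± 126 and 1458 ± 415 bp at E17.5. At Pik3ap1 (19:41272541-41385102), a signalling adaptor of leukocytes, the first step differed by 0.92, from 1139 ± 181.5 bp in males and 2043 ± 225 bp in females at E9.5 to 1215 ± 356 and 878 ± 25.5 bp at E12.5. The interaction of sex and stage (limma, 13656 promoters) passed at 2 promoters for the first step and 1 for the second, with 2317 and 1183 at an unadjusted p under 0.05. Both counts exceed the share of 0.05 that chance gives. At E12.5 every male library was deeper than every female one, with 23.7 to 35.2 against 19.3 to 23.2 megatags. Sex and depth can therefore not be told apart at E12.5. The sex of the genotype placentas is not given, and the Y-linked promoter Kdm5d was marked by H3K4me3Q5ser in 8 of these 12 placentas. These were 2 of 3 WT, 3 of 3 Sert KO, 2 of 3 Tph1 KO and 1 of 3 Oct3 KO placentas. Xist, which did not tell the sexes apart in the time course, was marked in 3, 1, 2 and 3 of 3. Marking of these genes was thus uneven over the genotypes, and sex was no covariate in the comparisons of knockouts.

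Promoters gained and lost between E9.5 and E17.5 were the first pattern weighed. The number of peaks per library was lower at E17.5. The gained promoters, a share of 0.276 of the 442, argue only against a lower peak number by itself, which can only take marks away. Peaks at E17.5 were also wider and more often at gene ends. Their median fold enrichment was 20.2 to 24.4 per library, against 13.4 to 17.4 at E9.5. Whether these differences added marks was not tested. For the 320 lost promoters a share of 0.487 (156) was still called with the same number of peaks in each library, and peak number stays open there as a candidate cause. Over gains and losses together the share was 0.593 (262), which decides nothing, because equal peak numbers favour gains (177 promoters more often marked). For the step from E9.5 to E12.5, 24 of the 96 lost promoters were still called at equal peak numbers, so that peak number stays open for these losses as well. Of the 51 gained, 34 were still called. Mean sequencing depth was highest at E12.5, with 24.7 megatags against 18.2 at E9.5 and 19.9 at E17.5. Depth was not tested as a cause of promoters gained at E12.5 or lost again at E17.5. Sequencing pool is argued against, as each pool held 4 placentas of every stage and the same 16 libraries split by pool gave 0 promoters by Fisher's exact test (6 at an unadjusted p under 0.05) against 442 by stage. The developmental stage itself stays open as a biological explanation.

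Spongiotrophoblast promoters gained over the time course were the second. Reads shared between near-identical copies of the Prl, Psg and Ceacam families might contribute to the gains. The test on the 4 members outside such families (Flt1, Ascl2, Pcdh12 and Gjb3) was void, with p = 1 (exact permutation test), because all were marked in 100% of placentas at every stage. Shared reads can therefore not be told apart from a change at each copy, and Tpbpa and Tpbpb were not tested for it. A change in the share or state of trophoblast cells was not tested.

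The excess of H3K4me3Q5ser over H3K4me3 promoters was the third. Fewer peaks in the H3K4me3 libraries may account for many of the 2414 calls, since a share of 0.141 of them (340) was still called with the same number of peaks in each library. That setting gave 888 of 1760 testable promoters, a share of 1 of them more often marked by H3K4me3Q5ser. This argues only against the number of peaks alone as the whole cause. Only 340 of the 888 were among the 2414, so it decides nothing for the other calls. The narrower peaks of the H3K4me3 libraries were not set aside. Antibody and peak caller version are confounded with the mark, so that a difference between the modifications themselves stays open and untested.

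Regrouping the same libraries showed whether chance can be excluded. For the stage comparisons of occupancy only the real one of 100 splits gave as many promoters, with 147, 35 and 442 against a highest other of 0 each. For stage widths only the real split of 100 gave as many, with 2299 against 1038 and 1895 against 787, and chance can be excluded for these as for sex (4 against 0) and for both marks (2414 against 778), each reached in 1 of 100 splits.

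With 3 against 3 there are 10 splits, too few for a share under 0.05. For promoters marked in 3 of 3 against 0 of 3, 2 of the 10 splits gave as many as Sert KO for H3K4me3Q5ser (45, highest other 180) and 6 for H3K4me3 (23 and 89), 4 and 7 for Tph1 KO (22 and 62; 12 and 62), and 6 and 4 for Oct3 KO (7 and 148; 43 and 74). The split with 180 set Sert KO replicates 689 and 718 with WT replicate 868 against the rest, which points to a structure of these samples other than genotype. These 3 libraries held the fewest peaks, 22311, 24785 and 24580, against 26494, 29019 and 33237 in the others, so the split follows peak number. For widths, 10 of 10 splits reached the real count of 0 in Sert KO (highest other 0 for H3K4me3Q5ser, 9 for H3K4me3 and 0 for the relative change), Tph1 KO (0, 1 and 0), Oct3 KO for H3K4me3Q5ser and the relative change (0 and 0) and Sert KO against Tph1 KO (0). Against Oct3 KO the highest other was 206, from the split of Sert KO replicates 689 and 718 with Oct3 KO replicate 700, again a structure other than genotype. These again held the fewest peaks, 22311, 24785 and 19633, against 26494, 28923 and 31407 in the others. For H3K4me3 in Oct3 KO 1 of 10 splits, the real one, gave 1 promoter, with a highest other of 0.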

How the results depend on the processing

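Depth limits what an absent peak means, since 8.43 to 25.4 megatags per time course library after removal of duplicates set which peaks were called, and 3 against 3 placentas cannot pass an exact test. Across 65 summary results and 227 comparisons with an alternative, 205 kept their call or stayed within 1.5 times the reported count, 22 moved and 0 reversed. For 164 genes named by occupancy, 926 of 984 comparisons kept the call, 45 lost it and 13 gained it, and for 93 genes named by width 841 of 851 kept it and 10 lost it. Where values moved, the cause was not tested unless stated. Alternatives chosen only after the results were seen are either gene end, pool or lane set and fragment length.

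With a 2 kb window E17.5 against E12.5 gave 76 promoters (30 more and 46 less often marked) and with either gene end 76 (27 and 49). With the same number of peaks per library, H3K4me3Q5ser against H3K4me3 gave 888, H3K4me3 in Tph1 KO 23 promoters in 3 of 3 against 0 of 3, gene lists by stage 5 calls (4 higher and 1 lower), and regions far from gene ends 392 and 1181. The same setting gave width calls of 2 for Sert KO in H3K4me3Q5ser (Hcn2 and Gm40814), 2 in H3K4me3 (Tesk2 and Hrob), and 1 against Tph1 KO and 1 against Oct3 KO (Hcn2), all lower in Sert KO. Peaks with -log10 q of 5 or more gave 70 promoters for Sert KO in H3K4me3Q5ser. An overlap of 200 bp gave 13 for Sert KO in H3K4me3 and 4 for Oct3 KO in H3K4me3Q5ser. The 1 width call of Oct3 KO in H3K4me3 became 0 with no scaling, a pseudocount of 50 bp, the lane set or fragment length. With no scaling the relative change in Sert KO had 1 call (Xaf1). Sex within a stage gave 0, 0 and 0, where the smallest p of 4 against 4 is 0.0286 (Fisher's exact test), so that a call would need a share of 0.571 of the testable promoters to separate fully. Without the replicate block, the interaction of genotype and mark gave 0, 0 and 0 calls, as with it, and with the block of placentas an exact McNemar test gave 2140 promoters for both marks against 2414. Stratified by pool, the stage counts were 141, 35 and 454, and sex 4.

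On leaving out 1 library, E12.5 against E9.5 ranged over 155 to 198 promoters, E17.5 against E9.5 over 466 to 498, widths over 1940 to 2253 and 1670 to 1855, both marks over 2419 to 2663, and lists by stage over 8 to 12. E17.5 against E12.5 ranged over 38 to 95, with 92 without E17.5M_36, 95 without E12.5F_80 or E12.5M_81, and 91 without E12.5F_79 or E12.5F_132. Slc22a3 width at E17.5 lost its call on leaving out any 1 of E17.5F_25, E17.5F_29, E17.5F_34, E17.5M_36, E17.5M_44, E17.5F_54, E17.5M_55, E12.5F_65, E12.5F_79, E12.5M_131 or E12.5F_132.

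Counts of 3 of 3 against 0 of 3 rise by construction when an arm holds 2 placentas. For Sert KO in H3K4me3Q5ser they ranged over 56 to 179 (72 without 689, 145 without 717, 73 without 718, 179 without WT 868) and in H3K4me3 over 32 to 1.3e+02 (49 without 689, 80 without 717, 64 without 718, 40 without WT 867, 1.3e+02 without 868). For Tph1 KO they ranged over 33 to 156 (46 without 674, 34 without 676, 49 without 684, 156 without 868, 38 without 873) and 30 to 117 (30, 31 and 37 without 674, 676 and 684, and 36, 117 and 51 without 867, 868 and 873). For Oct3 KO they ranged over 10 to 78 (19 without 697, 78 without 700, 11 without 867, 26 without 868) and 59 to 144 (120 without 697, 76 without 700, 89 without 867, 70 without 868, 144 without 873). Width calls ranged over 0 to 2 for Sert KO in H3K4me3 (2 without 717, Xaf1 and Chic1), 0 to 1 for its relative change (1 without 717, Chic1), 0 to 1 for Oct3 KO in H3K4me3Q5ser and for Sert KO against Oct3 KO (1 without 697), and 0 to 1 for Oct3 KO in H3K4me3 (0 without 700, 749, 867, 868 or 873). Non-overlapping lists by genotype ranged over 1 to 12, with 12 and 11 without WT 868, 10 of each lower in the knockout. The values that follow were read at an unadjusted p (exact permutation test). The gene-end share of peaks at E12.5 exceeded E9.5 by 2.71 to 4.27 points. Its p of 0.0458 with all libraries (exact permutation test) was over the threshold on leaving out any 1 of E12.5M_67, E12.5F_79, E12.5F_80, E12.5M_81, E12.5F_132, E9.5F_119, E9.5M_122, E9.5M_162, E9.5F_163 or E9.5F_181. The change in peaks from E12.5 to E17.5 was -1401 to -712 (passing without E12.5F_80), and that in median width 54 to 85 bp (passing without E17.5M_44 or E12.5F_80).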

Other observations

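All tests in this part were chosen only after the results were seen.

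Marked regions far from gene ends also differed between stages. Gene ends here are those of the 21886 genes used, nearly all protein-coding. Regions over noncoding genes, such as 1600012P17Rik and Neat1, were therefore kept, and their promoters were not set apart. Among 10551 regions more than 5 kb from any such end and marked in at least 2 libraries, H3K4me3Q5ser differed between E12.5 and E9.5 at 701 of 2702 testable regions (124 gained and 577 lost), between E17.5 and E12.5 at 89 of 1848 (37 and 52), and between E17.5 and E9.5 at 2011 of 3081 (418 and 1593; Fisher's exact test). Over the whole interval 82 regions went from 0 of 8 to 8 of 8 placentas and 264 the other way (p = 0.000155, adjusted p = 0.00138, exact). Gained regions included 1:158972030-158980491 (8462 bp) over the noncoding RNA gene 1600012P17Rik, 8:25531931-25535520 (3590 bp) in Fgfr1, the gene of a fibroblast growth factor receptor, X:145477515-145480587 in Amot, and 7:17087914-17090837 in Psg16 and 7:17672215-17675332 in Psg-ps1, whose near-identical copies can share reads. Lost regions included 19:5826901-5832780 (5880 bp) over Neat1, the noncoding RNA of paraspeckles, 12:34710968-34714685 in the histone deacetylase gene Hdac9, 8:79369174-79372535 in Smad1, which carries BMP signals, X:159458866-159462540 in Map7d2 and 12:112784656-112788018 in Ahnak2. With the same number of peaks per library the splits were 168 and 224, 42 and 41, and 489 and 692. In 100 splits of the libraries, 1 (the real one) gave as many regions for each comparison, with a highest other of 0 against 701, 89 and 2011, so chance can be excluded.

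Gene families taken by symbol, some of which overlap the lists, were compared with all 742 promoters testable between E9.5 and E17.5, in 14 Fisher's exact tests. Placental multigene families supplied 19 gained promoters of 21 testable (expected 3.45, odds ratio 57, adjusted p = 8.0e-13, Fisher's exact test). They supplied 2 lost ones, Prl7a1 and Prl8a2, against an expected 9.06 (odds ratio 0.133, adjusted p = 0.00582, Fisher's exact test). Many of the gained members, such as Psg25, Prl8a6 and Cts6, were already named as gains. The test also counts near-identical copies as separate genes, so it restates these gains and gives no separate support. Homeobox genes supplied 11 gained promoters of 22 testable against an expected 3.62 (odds ratio 5.49, adjusted p = 0.00153), namely Cdx1, Evx1, Hoxa2, Hoxc8, Irx4, Lhx8, Lmx1b, Pax8, Pitx1, Six6 and Uncx, and 5 lost ones (adjusted p = 0.149). An excess of homeobox promoters among the gains of this interval may be one hypothesis, found and tested on the same data, and the fixed lists of Hox genes and neural transcription factors did not pass at either step. Receptors for neurotransmitters and neuropeptides had 12 of 18 testable promoters among those lost (expected 7.76, odds ratio 2.70, Fisher's exact p = 0.0531, adjusted p = 0.149), among them Gabrb2, Gabrg1, Gabrq, Grik1, Grin3b, Grm7, Htr1f, Mc4r and Npy1r, so that an excess of receptors among the losses was not shown. No other family had an adjusted p under the threshold: channels had 5 lost and 0 gained promoters, cadherins 4 and 2, Slc transporters 7 and 3, and interferon-inducible genes 6 and 1.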
